A study of Mus musculus with 40 samples.

How the data were processed

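The values used here are the FPKM table deposited by the authors, with 54532 genes in 40 libraries. Per the submitters' processing notes, RNA was poly-T-selected and the tools listed are CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with the mouse assembly GRCm38 (mm10). The step each tool was used for is not given in the sources used here. Group, genotype and day were read from the series labels, and the groups and contrasts were fixed before the data were examined, as were the alternatives except those named below as added. The identifiers matched GENCODE M21 for 99.8 percent of genes.

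The FPKM carried a scaling by median of ratios: whole reads could be recovered for every nonzero value, within 0.001 read, with 1 constant of 1.0169 for all libraries. Values divided by that constant are called scaled FPKM. The recovered reads gave 9156431 to 14058050 fragments a library, or 3577936 to 9365306 without hemoglobin, and 1 read of a 2 kb gene is 0.0189 to 0.103 FPKM. Genes at 1 FPKM or more in at least 3 libraries were kept (11772). A single fit of log2(scaled FPKM + 1) over 8 groups was made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 per contrast. Interactions are differences between 2 such contrasts. Standard errors of log2 changes come from this fit, and groups are given as mean ± SD over mice.

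There were 30 gene lists written from general knowledge of blood cells and pathways, each tested with camera at a preset correlation of 0.01, adjusted over the lists. Each call was repeated with the correlation estimated from the data and with fry. Counts adjusted over the list alone use the p values of the members of 1 list. The interferon score per mouse was compared by exact two-sided permutation of mice, adjusted over 10 contrasts. Library measures were compared by the same test, adjusted over 30.

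Genes are named in the text if they had a mean of at least 5 FPKM in a group and were among the 8 highest or lowest folds of the called genes, or among the 4 members of a list with the smallest p. The first rule left out predicted genes, receptor and antibody segments, and sex-linked marker genes. Another 10 genes are always in the tables. Exceptions are said where they occur, and 2 genes are not reported here. Shared controls were handled by simulating unchanged groups with the same PBS mice and by splitting the controls 3 and 3.

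Alternatives tried were a fixed total with or without hemoglobin, a pseudocount of 0.1, no filter, a fit of only the groups compared, arrayWeights, voom on recovered reads, another list of interferon genes, leaving out each library in turn, and leaving out 7 libraries whose mitochondrial share of non-hemoglobin fragments was under 1.2 percent. The fixed total with hemoglobin, voom and the 7 libraries were added after values had been seen. In a self-test, changes were added to 100 genes per size: 68 to 84 percent were recovered at log2 1 and 88 to 97 percent at log2 2, with 3.11 to 7.25 percent of calls false. Its noise was drawn independently for each gene, so it does not give the share of false calls in libraries whose genes vary together. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.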

Results

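Whole-blood mRNA was profiled in 40 mice to follow the response to pristane, an oil that brings on lupus-like disease. The groups differed in genotype for Ifnar1, a type I interferon receptor gene, and in whether spermine was given beforehand. Uninduced mice (3 Ifnar1+/+ and 3 labelled Ifnar1-/-) were set beside Ifnar1+/+ mice given PBS or spermine for 3 days and bled on day 4 or day 6 of pristane (6 each). PBS-treated mice labelled Ifnar1-/- were bled on the same days (5 each). The labels give no pretreatment for uninduced mice. Pristane and the PBS given beforehand thus cannot be told apart where mice are compared with uninduced ones. Hemoglobin transcripts took 26.5 to 62.2 percent of the fragments of a library. Ifnar1 itself had a higher whole-gene value in the 13 mice labelled Ifnar1-/- (18.1 ± 2.76 FPKM as deposited, mean ± SD, range 13.7 to 23.9) than in the 27 Ifnar1+/+ mice (8.36 ± 1.01, range 5.85 to 10.3). In PBS-treated mice it was 20.6 ± 1.87 against 8.25 ± 0.76 FPKM on day 4 and 16.5 ± 1.84 against 8.07 ± 1.00 on day 6. Each difference had p = 0.0022 (exact permutation, two-sided, the smallest that 5 against 6 mice can give) and p = 0.0325 adjusted over 30 tests, with 5 of 5 mice higher. The whole-gene value separates the genotypes but does not show loss of the transcript, so these mice are called labelled Ifnar1-/-.

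**Figure D1:**
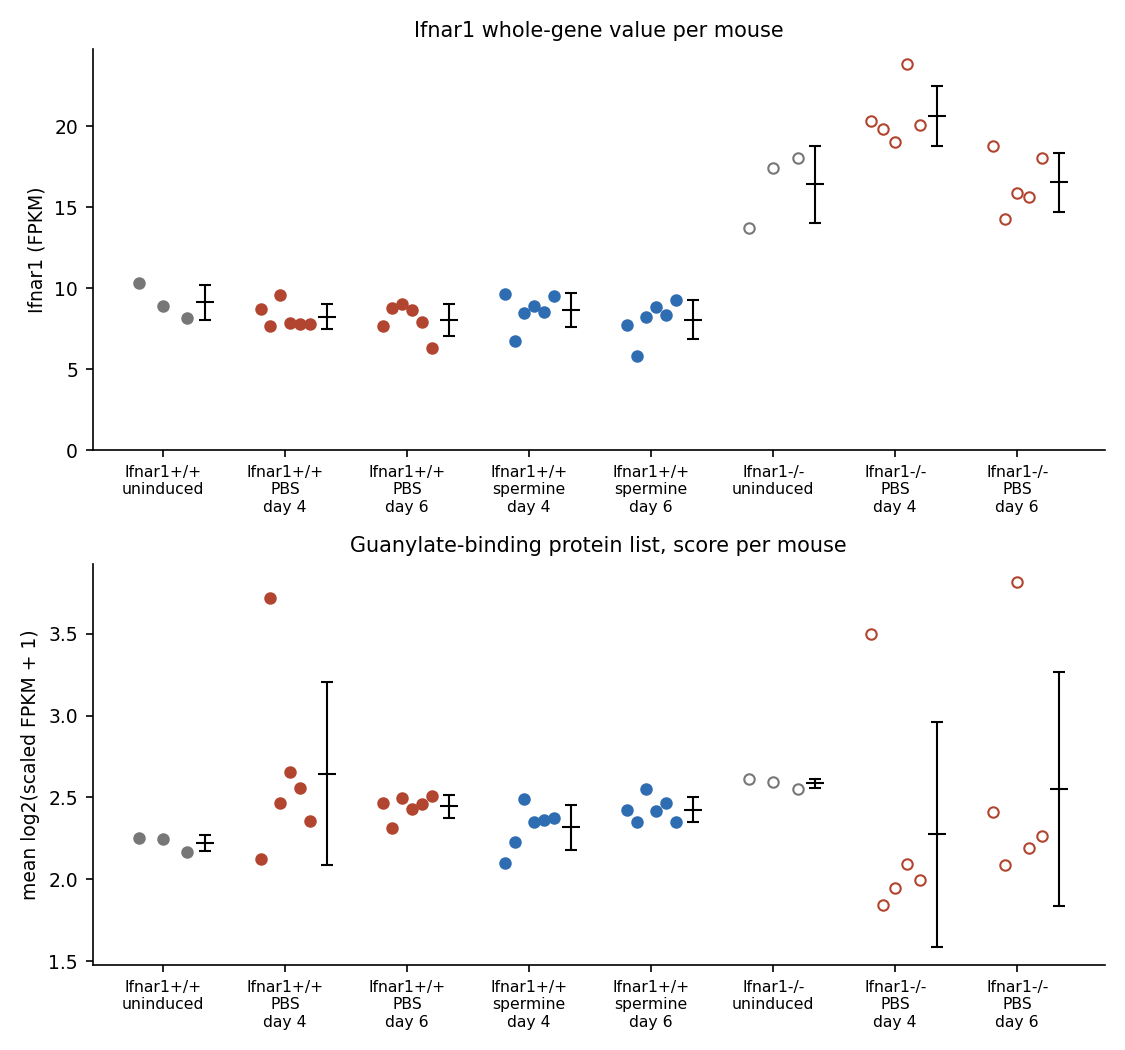
Ifnar1 FPKM as deposited (top) and mean log2(scaled FPKM + 1) of the guanylate-binding protein list (19 genes, bottom) in each mouse (points: filled, Ifnar1+/+, open, labelled Ifnar1-/-, grey, uninduced, red, PBS, blue, spermine), with group mean and SD (bars). Ifnar1 spans 13.7 to 23.9 in mice labelled Ifnar1-/- and 5.85 to 10.3 in Ifnar1+/+ mice, and the list is at 3.50 and 3.81 in 2 mice labelled Ifnar1-/-.

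On day 4 of pristane, blood of Ifnar1+/+ mice held more neutrophil and granule transcripts and fewer natural killer cell transcripts than that of uninduced mice. Lcn2, which encodes an iron-scavenging granule protein, changed by 2.46 ± 0.31 (log2 change ± SE, adjusted p = 5.97e-06, 6 and 3 mice), beside the surface marker Ly6g (2.48 ± 0.46) and the collagenase gene Mmp8 (2.01 ± 0.36). In the neutrophil list, 15 of 21 genes rose and 6 were not called (17 higher and 1 lower adjusted over the list alone), with a median log2 change of 1.28 (camera, adjusted p = 2.54e-24). Of 6 genes of neutrophil formation 5 rose (5 adjusted over the list alone, median 1.54), such as the granule genes Ngp (2.47 ± 0.42) and Ltf (2.03 ± 0.34). Of 11 Fc receptor and complement genes 6 rose (8 adjusted over the list alone, median 0.85), such as C3 (1.70 ± 0.24) and Fcgr3 (0.93 ± 0.21). Of 17 glycolysis genes 3 rose (8 adjusted over the list alone, median 0.42), such as the lactate exporter gene Slc16a3 (1.14 ± 0.19). Natural killer and cytotoxic genes went the other way, with 6 of 15 lower (12 adjusted over the list alone, median -0.86, adjusted p = 1.68e-15), such as the receptor genes Klrd1 (-1.18 ± 0.24) and Klre1 (-1.28 ± 0.19). Ear1, an eosinophil ribonuclease gene, was listed at 0 in the 3 uninduced mice and at 6.30 ± 3.09 scaled FPKM (mean ± SD) on day 4. Most single-gene calls ended under other settings. With a fixed total without hemoglobin 1 neutrophil gene, 2 genes of neutrophil formation, 1 Fc receptor or complement gene and 6 natural killer genes were called, with list medians of 1.00, 1.27, 0.56 and -1.01, and 0.11 for glycolysis. Ly6g, Mmp8, Fcgr3, Slc16a3 and Klrd1 lost their calls there, and Lcn2, Ly6g, Ngp, Fcgr3, Slc16a3 and Klrd1 in a fit of only the groups compared, which called 17 genes.

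Interferon-stimulated genes stood higher on day 4 as a group, although few passed the test singly. Of 48 members 5 rose and 43 were not called (30 rose adjusted over the list alone). The median log2 change was 0.72 (camera, adjusted p = 7.28e-18), and adjusted p = 0.136 with an estimated correlation. The nucleotide kinase gene Cmpk2 (1.14 ± 0.30), the antiviral gene Oasl1 (1.11 ± 0.29) and the RNA helicase gene Dhx58 (1.04 ± 0.19, adjusted p = 0.0013) were among them. Isg15, which encodes a ubiquitin-like protein (0.87 ± 0.51, adjusted p = 0.457), and the transcription factor gene Irf7 (1.09 ± 0.47, adjusted p = 0.267) were not called. Cmpk2, Oasl1 and Dhx58 lost their calls with a fixed total without hemoglobin and in a fit of only the groups compared. The mean log2 value of the list per mouse was 4.04 ± 0.36 on day 4 and 3.28 ± 0.10 in uninduced mice (exact permutation, two-sided, p = 0.0238, adjusted over 10 comparisons 0.0476), with 6 of 6 mice above all 3. Over all 11772 genes tested, 199 rose and 48 fell. With each library scaled to a fixed total without hemoglobin, the median of all genes shifted to -0.20 and the split was 13 up and 26 down. Relative to that median the interferon list stood at 0.67 and the natural killer list at -0.81. All 25 erythroid genes had changes above 0 as well, without a call of a single gene (median 0.61, camera adjusted p = 0.0013), list adjusted p = 0.547 with an estimated correlation, and the median was 0.12 without the 7 libraries of low mitochondrial share. The count of 247 was 131 without uninduced Ifnar1+/+ mouse 1, 113 without mouse 3 and 145 without day 4 mouse 5.

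**Figure D2:**
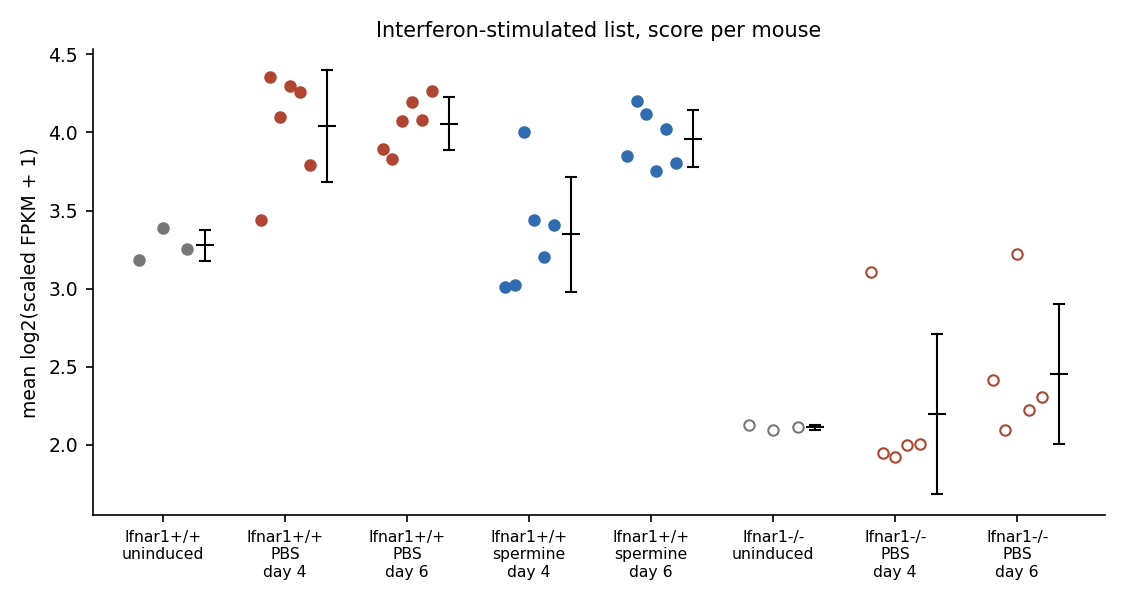
Mean log2(scaled FPKM + 1) of the interferon-stimulated list (48 genes) in each mouse (points: filled, Ifnar1+/+, open, labelled Ifnar1-/-, grey, uninduced, red, PBS, blue, spermine), with group mean and SD (bars). Uninduced Ifnar1+/+ mice average 3.28, those on day 4 of pristane 4.04 after PBS and 3.35 after spermine, a difference whose list median turns from -0.45 to 0.15 with a fixed total without hemoglobin, where the median of all genes moves to 0.51 alike and the list stands at -0.36 relative to it, and uninduced mice labelled Ifnar1-/- 2.11.

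By day 6 the calprotectin genes and other neutrophil genes stood far above their uninduced values in Ifnar1+/+ mice. S100a9 was at 2033 ± 841 against 225 ± 73.7 scaled FPKM in uninduced mice (3.08 ± 0.39, adjusted p = 8.81e-07), and S100a8 (3.08 ± 0.40) and Lcn2 (3.57 ± 0.31) rose too. Of the 21 neutrophil genes 19 rose and 2 were not called (20 higher and 1 lower adjusted over the list alone, median 2.11, adjusted p = 1.67e-34). Fc receptor and complement genes (8 of 11 up, 9 adjusted over the list alone, median 1.36, Fcgr3 1.54 ± 0.21) and glycolysis genes (11 of 17 up, 11 adjusted over the list alone, median 0.57, Slc16a3 1.71 ± 0.19) rose as well. So did 4 of 6 genes of neutrophil formation (5 adjusted over the list alone, median 1.42). Of 12 genes of Ly6C-high monocytes, the inflammatory type, 8 rose (9 adjusted over the list alone, median 1.01), such as Ccr2 (1.30 ± 0.25) and Ly6c2 (2.07 ± 0.36), list adjusted p = 0.114 with an estimated correlation. Of 17 B cell genes 5 fell (6 adjusted over the list alone, median -0.29), such as Cd22 (-0.48 ± 0.12) and Fcer2a (-0.47 ± 0.13), list adjusted p = 0.263 with an estimated correlation. Of 15 natural killer genes 3 fell (3 adjusted over the list alone, median -0.35), list adjusted p = 0.441 with an estimated correlation. Ccr2, Cd22 and Fcer2a lost their calls with a fixed total without hemoglobin, and Ccr2 and Cd22 in a fit of only the groups compared.

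Interferon-stimulated genes also stood above their uninduced values on day 6. Of 48 genes 15 rose and 33 were not called (24 rose adjusted over the list alone). The median was 0.67 (camera, adjusted p = 6.09e-10), and adjusted p = 0.349 with an estimated correlation. Oas1a, which senses viral RNA (1.89 ± 0.34, adjusted p = 0.000234), Ifit1 (1.66 ± 0.52, adjusted p = 0.0423) and Irf7 (1.55 ± 0.47, adjusted p = 0.0345) rose, and Isg15 stood at 1.49 ± 0.51 (adjusted p = 0.0601). Ifit1 and Irf7 lost their calls with a fixed total without hemoglobin, in a fit of only the groups compared and without the 7 libraries of low mitochondrial share. The score per mouse was 4.06 ± 0.17 (exact permutation, two-sided, p = 0.0119, the smallest these group sizes can give, adjusted 0.0298), with 6 of 6 mice above all uninduced ones. In all, 661 genes rose and 305 fell. Scaled to a fixed total with hemoglobin, the split was 49 and 8, the median of all genes -0.12, and the neutrophil list 1.98 relative to it. The count of 966 was 456 without uninduced mouse 1 and 487 without uninduced mouse 3.

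Set directly against day 4, neutrophil genes stood higher on day 6 as a list, and the calls of single genes depended on the processing. The decoy receptor gene Il1r2 (0.97 ± 0.18), the chemokine receptor gene Ccr1 (0.89 ± 0.15), the interleukin 1 antagonist gene Il1rn (0.79 ± 0.14), Trem1 (0.74 ± 0.13) and Lcn2 (1.11 ± 0.25) rose, and Ear1 (-1.89 ± 0.30) fell. In the neutrophil list 6 of 21 genes rose (18 adjusted over the list alone, median 0.93, camera adjusted p = 1.98e-19), list adjusted p = 0.0833 with an estimated correlation. The interferon list had a median of -0.05 (adjusted p = 0.588), which was -0.13 (adjusted p = 0.00991) without day 4 mouse 1. It was 0.048 without day 4 mouse 2, and the list was called as lower without the 7 libraries of low mitochondrial share. Its score per mouse differed by 0.02 (exact permutation, two-sided, p = 0.933, adjusted 1). The gene count of 56 (36 up, 20 down) rests on single mice. Without day 4 mouse 1, 2, 3, 4 or 5 it was 24, 24, 36, 25 or 339, and without day 6 mouse 1, 2, 5 or 6 it was 34, 31, 26 or 116. Limma called 0 genes with a fixed total without hemoglobin (970 at an unadjusted p below 0.05) and 0 in a fit of only the groups compared (1725), and it called 6 without the 7 libraries of low mitochondrial share.

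In mice labelled Ifnar1-/-, neutrophil and monocyte genes were also higher on day 4 of pristane than in uninduced mice. Ly6g was at 49.5 ± 9.07 against 1.05 ± 0.43 scaled FPKM in uninduced mice of that genotype (4.62 ± 0.47, adjusted p = 4.84e-09, 5 and 3 mice), and Lcn2 changed by 4.07 ± 0.32. The neutrophil list had 19 genes up and 1 down of 21 (19 and 1 adjusted over the list alone, median 2.40, adjusted p = 1.6e-42). Genes of neutrophil formation (5 of 6 up, 5 adjusted over the list alone, median 2.67, Ngp 4.33 ± 0.43) and of Ly6C-high monocytes (10 of 12 up, 11 adjusted over the list alone, median 1.04, Ccr2 2.17 ± 0.26) rose. So did Fc receptor and complement genes (6 of 11 up, 9 adjusted over the list alone, median 1.00, C3 2.25 ± 0.25) and glycolysis genes (10 of 17 up, 12 adjusted over the list alone, median 0.59, Hk3 2.15 ± 0.20). Of 23 inflammatory genes of the NF-kB pathway 8 rose (10 adjusted over the list alone, median 0.21), such as the endotoxin coreceptor gene Cd14 (2.08 ± 0.34), list adjusted p = 0.0907 with an estimated correlation. Of 15 natural killer genes 8 fell (10 adjusted over the list alone, median -0.60), such as the chemokine gene Ccl5 (-1.78 ± 0.41), list adjusted p = 0.132 with an estimated correlation. Of 7 hemoglobin genes 3 fell (6 adjusted over the list alone, median -1.44), such as Hbb-bt (-1.62 ± 0.40), list adjusted p = 0.15 with an estimated correlation.

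The interferon list was not called in mice labelled Ifnar1-/- on day 4, where 1 mouse stood apart. Trim30a (0.78 ± 0.21) and Dhx58 (0.69 ± 0.20) rose and Ifi209 (-0.53 ± 0.15) fell among 48 genes (2 up and 1 down adjusted over the list alone), with a median of 0.06 (adjusted p = 0.624). Dhx58 and Ifi209 lost their calls with a fixed total without hemoglobin, and Ifi209 turned to 0.12 with hemoglobin included. The score was 2.20 ± 0.51 against 2.11 ± 0.017 (exact permutation, two-sided, p = 1, adjusted 1). Mouse 1 scored 3.11 and the other 4 mice 1.92 to 2.01, below all 3 uninduced mice (2.10 to 2.13), and without mouse 1 the list median turned to -0.12 (adjusted p = 0.182). In all, 780 genes rose and 176 fell. Scaled to a fixed total with hemoglobin, the split was 2332 and 30, the median of all genes 0.44, and the neutrophil list 2.62 relative to it.

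On day 6, erythroid and platelet genes were raised in mice labelled Ifnar1-/- beside the neutrophil genes. No hemoglobin gene was called (list median 0.19, camera adjusted p = 0.615). In the erythroid list 14 of 25 genes rose and 11 were not called (16 rose adjusted over the list alone, median 1.43, camera adjusted p = 2.72e-10), list adjusted p = 0.29 with an estimated correlation. The membrane gene Epb42 (2.78 ± 0.59, adjusted p = 0.0012) and the transferrin receptor gene Tfrc (1.43 ± 0.26) were among them. Of 15 platelet genes 8 rose (11 adjusted over the list alone, median 0.74), such as Thbs1 (1.51 ± 0.35, not called in a fit of only the groups compared), list adjusted p = 0.29 with an estimated correlation. Ifnar1+/+ mice on day 6 also had higher erythroid and platelet lists (medians 0.51 and 0.43, camera adjusted p = 0.0083 and 0.0088), neither called with an estimated correlation. The erythroid score on day 6 was 6.37 ± 0.55 in mice labelled Ifnar1-/- and 6.16 ± 0.92 in Ifnar1+/+ mice. Neutrophil genes (19 of 21 up, 19 adjusted over the list alone, median 2.25, Ly6g 4.70 ± 0.47) and glycolysis genes (11 of 17, 12 adjusted over the list alone, median 0.57, Slc16a3 1.74 ± 0.20) were up. Of 17 B cell genes 7 fell (14 adjusted over the list alone, median -0.50), such as Cd22 (-0.56 ± 0.13), list adjusted p = 0.0736 with an estimated correlation. Of 15 natural killer genes 7 fell (7 lower and 1 higher adjusted over the list alone, median -0.63), such as the transcription factor gene Tbx21 (-1.27 ± 0.24), list adjusted p = 0.29 with an estimated correlation.

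Of 48 interferon-stimulated genes 4 rose in mice labelled Ifnar1-/- by day 6, among them Isg15 (1.73 ± 0.52, adjusted p = 0.0266), Rsad2, which encodes an antiviral enzyme (1.72 ± 0.59, adjusted p = 0.0499), and Trim30a (0.66 ± 0.21). Rsad2 and Isg15 ran with the erythroid score within groups (slopes 1.35 ± 0.05 and 0.87 ± 0.16, SE), and Trim30a did not (-0.03 ± 0.09). The erythroid list rose in the same comparison (median 1.43). For Rsad2 and Isg15 more red-cell RNA thus cannot be told apart from an interferon response. Isg15 and Trim30a lost their calls in a fit of only the groups compared, Trim30a with a fixed total without hemoglobin and Rsad2 with a pseudocount of 0.1. The list median of 0.25 (camera, adjusted p = 0.049) had adjusted p = 0.699 with an estimated correlation. Leaving out uninduced mouse 1, 2 or 3 took its adjusted p to 0.0806, 0.0538 or 0.0534, and leaving out day 6 mouse 1 or 3 to 0.0524 or 0.572. The median was 0.10 without day 6 mouse 3, and the list was not called without the 7 libraries of low mitochondrial share. The score was 2.45 ± 0.45 (exact permutation, two-sided, p = 0.268, adjusted 0.383). In all, 1012 genes rose and 379 fell, and the count of 1391 was 722 without uninduced mouse 2 and 754 without mouse 3. Scaled to a fixed total without hemoglobin, the split was 430 and 1756, the median of all genes -0.33, and the erythroid list 1.36 relative to it.

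Before pristane, interferon-stimulated genes were lower in mice labelled Ifnar1-/- than in Ifnar1+/+ mice. Isg15 was at 16.1 ± 2.09 against 332 ± 227 scaled FPKM (-4.07 ± 0.58, adjusted p = 0.000139, 3 and 3 mice), Irf7 at 2.73 ± 0.563 against 67.4 ± 33.3 (-4.07 ± 0.54), and Ifit1 changed by -3.37 ± 0.60. Of 48 genes 11 fell and 37 were not called (33 fell adjusted over the list alone, median -0.77, camera adjusted p = 1.31e-35), list adjusted p = 0.0699 with an estimated correlation. All 3 mice scored below all 3 Ifnar1+/+ mice (2.11 ± 0.017 against 3.28 ± 0.10, exact permutation, two-sided, p = 0.1, the smallest 3 against 3 can give, adjusted 0.167). The erythroid list was lower too, without a call of a single gene (median -0.57, camera adjusted p = 0.000184), list adjusted p = 0.706 with an estimated correlation. Of 18 T cell genes 1 was higher (4 adjusted over the list alone, median 0.33), list adjusted p = 0.37 with an estimated correlation. The ribosomal protein list had a median of 0.29 (camera adjusted p = 0.0011), list adjusted p = 0.785 with an estimated correlation. The neutrophil list was higher (median 0.36, camera adjusted p = 0.000772) and the B cell list lower (median -0.16, camera adjusted p = 0.0014). Neither was called with an estimated correlation, and the B cell median was 0.001 with a fixed total without hemoglobin. Among the 27 genes that rose were Jchain, which joins antibody units (2.22 ± 0.38), the lymphocyte receptor gene Klrg1 (1.92 ± 0.33) and Ifnar1 (0.78 ± 0.14, adjusted p = 0.0022), which lost its call with a fixed total without hemoglobin. Another 21 fell, and with a fixed total including hemoglobin the split was 8 up and 14 down. Without hemoglobin in the total, the median of all genes was 0.12 and the interferon list -0.79 relative to it. The count of 48 was 27 without uninduced Ifnar1+/+ mouse 3 or labelled Ifnar1-/- mouse 1, and 30 without labelled Ifnar1-/- mouse 3. In a fit of only the groups compared limma called 0 genes (1191 at an unadjusted p below 0.05), which ends each single-gene call given here.

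On day 4 of pristane nearly the whole interferon list was lower in mice labelled Ifnar1-/-. Isg15 stood at 11.9 ± 10.7 against 553 ± 215 scaled FPKM (-5.65 ± 0.43, adjusted p = 5.14e-11, 5 and 6 mice), and Irf7 (-4.97 ± 0.40), Ifit1 (-4.33 ± 0.45) and Rsad2 (-4.17 ± 0.49) were lower too. Of 48 genes 46 were lower and 2 not called (47 lower adjusted over the list alone, median -1.38, adjusted p = 8.67e-46). The score was 2.20 ± 0.51 against 4.04 ± 0.36 (exact permutation, two-sided, p = 0.0022, the smallest these sizes can give, adjusted 0.0108), with 5 of 5 mice below all 6. Neutrophil genes were higher (20 of 21, 20 adjusted over the list alone, median 1.70, Ly6g 2.37 ± 0.39). Fc receptor and complement genes had 8 up and 1 down of 11 (9 and 1 adjusted over the list alone, median 0.67), list adjusted p = 0.0871 with an estimated correlation. Inflammatory NF-kB genes had 8 up and 1 down of 23 (10 and 1 adjusted over the list alone, median 0.29), list adjusted p = 0.112 with an estimated correlation. Of 13 eosinophil and basophil genes 7 were higher (7 higher and 2 lower adjusted over the list alone, median 0.74), such as the receptor gene Ccr3 (1.53 ± 0.27), list adjusted p = 0.183 with an estimated correlation.

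Red-cell genes were lower in mice labelled Ifnar1-/- on day 4. In the erythroid list 22 of 25 were lower (22 adjusted over the list alone, median -1.85, camera adjusted p = 6.65e-15), such as Alas2, the first enzyme of heme synthesis (-2.02 ± 0.37), list adjusted p = 0.161 with an estimated correlation. All 7 hemoglobin genes were lower (7 adjusted over the list alone, median -1.52), list adjusted p = 0.113 with an estimated correlation. Of 18 polyamine genes 3 were higher and 6 lower (4 and 6 adjusted over the list alone, adjusted p = 0.403), and the median of -0.06 turned to 0.47 with a fixed total without hemoglobin (0.02 relative to all genes). The spermine oxidase gene Smox (-1.59 ± 0.36) and the ornithine decarboxylase gene Odc1 (-0.98 ± 0.25) were lower and the acetyltransferase gene Sat1 (0.85 ± 0.21) higher, and all 3 lost their calls without the 7 libraries of low mitochondrial share. Odc1 was not called with a fixed total without hemoglobin and turned to 0.040 with hemoglobin included. In all, 1091 genes were higher and 1095 lower. With a fixed total without hemoglobin the median of all genes moved to 0.45 and the split to 6622 and 428. Relative to that median the interferon list stood at -1.29, the erythroid list at -1.63 and the neutrophil list at 1.88. Without the 7 libraries of low mitochondrial share, 3 of them from Ifnar1+/+ mice on day 4, the split was 510 and 305 and the erythroid median -0.94.

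On day 6 interferon-stimulated genes again stood lower in mice labelled Ifnar1-/-, such as Irf7 (-5.16 ± 0.40), Ifit1 (-4.44 ± 0.45) and Isg15 (-3.84 ± 0.43). Of 48 genes 37 were lower and 11 not called (44 lower adjusted over the list alone, median -1.14, adjusted p = 5.36e-70). The score was 2.45 ± 0.45 against 4.06 ± 0.17 (exact permutation, two-sided, p = 0.0022, adjusted 0.0108), with 5 of 5 mice below all 6. Atf5 (2.70 ± 0.38), a stress-response transcription factor gene, and Asns, which makes asparagine (2.23 ± 0.31), were among the most raised. Of 21 neutrophil genes 4 were higher (14 adjusted over the list alone, median 0.59), list adjusted p = 0.146 with an estimated correlation. Of 6 genes of neutrophil formation 3 were higher (4 adjusted over the list alone, median 0.98), such as Camp (1.44 ± 0.29), list adjusted p = 0.066 with an estimated correlation. Eosinophil and basophil genes had 6 of 13 higher (6 adjusted over the list alone, median 0.71, Ccr3 1.06 ± 0.27), list adjusted p = 0.0612 with an estimated correlation. B cell genes had 5 of 17 lower (10 adjusted over the list alone, median -0.35), such as Ms4a1, which encodes CD20 (-0.82 ± 0.13), list adjusted p = 0.0612 with an estimated correlation. In all, 179 genes were higher and 198 lower (28 and 56 with a fixed total including hemoglobin). Ccr3 lost its call with a fixed total without hemoglobin, and Ccr3 and Camp in a fit of only the groups compared. The count of 377 was 246 without Ifnar1+/+ day 6 mouse 6 and 231 without labelled Ifnar1-/- day 6 mouse 1.

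The pristane response was compared between the genotypes as an interaction, whose single-gene calls rest on single mice. On day 4 Steap4, a metalloreductase gene (1.84 ± 0.39, difference of log2 changes, adjusted p = 0.0335), Ccr1 (1.42 ± 0.27), Hk3 (1.36 ± 0.27) and Cxcr2 (1.32 ± 0.29) were among 28 genes that rose more, and 2 rose less. Of 21 neutrophil genes 2 rose more (15 adjusted over the list alone, median 1.22, camera adjusted p = 7.1e-19), list adjusted p = 0.0943 with an estimated correlation. The interferon list had a median difference of -0.66 (camera, adjusted p = 1.76e-10, 0.243 with an estimated correlation), which turned to 0.03 with a fixed total including hemoglobin, or -0.63 relative to the median of all genes there (0.66). The gene count of 30 was 1 without labelled Ifnar1-/- day 4 mouse 3, 4 or 5, 2, 10 or 2 without uninduced mouse 1, 2 or 3 of that label, and 2, 19 or 5 without uninduced Ifnar1+/+ mouse 1, 2 or 3. Without Ifnar1+/+ day 4 mouse 1, 2, 3, 4 or 5 it was 7, 17, 16, 7 or 128. With voom limma called 0 genes (1027 at an unadjusted p below 0.05), and the 4 genes named here lost their calls without the 7 libraries of low mitochondrial share. A fixed total including hemoglobin gave 569 up and 5 down, with the median of all genes at 0.66. On day 6, S1pr5 (-1.66 ± 0.30, adjusted p = 0.0139) and Klrg1 (-2.14 ± 0.41, adjusted p = 0.0312), genes of cytotoxic lymphocytes, were called beside Mir6907, named after its value was seen, among 3 genes (1 up and 2 down, 2 and 2 with a fixed total without hemoglobin, where the median of all genes was -0.16). Both genes already stood higher in uninduced mice labelled Ifnar1-/- (1.54 ± 0.24 and 1.92 ± 0.33), and S1pr5 was at 8.80 ± 1.19 scaled FPKM there and 3.21 ± 0.797 on day 6, against 2.50 ± 1.19 and 3.62 ± 1.06 in Ifnar1+/+ mice. The interferon list stood at -0.35 (camera, adjusted p = 4.87e-06), list adjusted p = 0.7 with an estimated correlation. It stood at -0.57 without labelled Ifnar1-/- day 6 mouse 3. The erythroid list stood at 0.78 (camera, adjusted p = 1.2e-06), MHC class I at -0.46 and Ly6C-low monocytes at -0.70 (both 4.59e-05). None of these lists was called with an estimated correlation. That count of 3 was 1 without uninduced Ifnar1+/+ mouse 3 and 6 without labelled Ifnar1-/- day 6 mouse 4, and limma called 0 genes with a pseudocount of 0.1 (591 at an unadjusted p below 0.05) and in a fit of only the groups compared (558).

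Spermine before pristane went with far fewer red-cell transcripts on day 4. The anion exchanger gene Slc4a1 was at 30.7 ± 14.1 against 430 ± 292 scaled FPKM after PBS (-3.59 ± 0.47, adjusted p = 2.33e-06, 6 and 6 mice). The membrane gene Epb42 changed by -3.34 ± 0.46. In the erythroid list 22 of 25 genes fell and 3 were not called (24 fell adjusted over the list alone, median -2.64, camera adjusted p = 5.09e-38), list adjusted p = 0.0775 with an estimated correlation. Of 7 hemoglobin genes 6 fell (7 adjusted over the list alone, median -1.49), such as Hbb-bt (-2.04 ± 0.32), list adjusted p = 0.0901 with an estimated correlation. Hemoglobin took 39.9 ± 8.45 percent of fragments against 51.1 ± 3.71 (exact permutation, two-sided, p = 0.0087, adjusted over 30 tests 0.0731). The mitochondrial share of the other fragments was 2.00 ± 0.38 percent against 1.25 ± 0.41 (exact permutation, two-sided, p = 0.013, adjusted 0.0731). With a fixed total without hemoglobin the median of all genes shifted to 0.51, and relative to it the erythroid list stood at -2.49 and the hemoglobin list at -1.27.

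Several strongly expressed interferon-stimulated genes were lower after spermine on day 4. Isg15 was at 50.2 ± 17.6 against 553 ± 215 scaled FPKM (-3.42 ± 0.41, adjusted p = 1.41e-06), Rsad2 at 99.7 ± 55.9 against 934 ± 627 (-3.07 ± 0.46) and Irf7 at 20.8 ± 10.0 against 143 ± 68.8 (-2.70 ± 0.38). Ifit1 changed by -1.89 ± 0.43 (adjusted p = 0.0022), while Mx1 (-0.39 ± 0.21, adjusted p = 0.344) was not called. Ifit1 lost its call without the 7 libraries of low mitochondrial share. Of 48 members 12 fell and 36 were not called (17 fell adjusted over the list alone). The median of -0.45 (camera, adjusted p = 1.67e-12, 0.318 with an estimated correlation) turned to 0.15 with a fixed total without hemoglobin and 0.39 with hemoglobin included, or -0.36 and -0.31 relative to all genes. The score per mouse was 3.35 ± 0.37 against 4.04 ± 0.36 (exact permutation, two-sided, p = 0.0108, adjusted 0.0298), with 5 of 6 mice below all 6 PBS mice. Across the 48 members, which are not independent replicates, the spermine change ran with the slope of each gene on the erythroid score within groups (r = -0.82, rho = -0.53, permutation p = 1e-05, the smallest the permutations can give). Jak1, the kinase in the title of the series, stood at -0.03 ± 0.12 (adjusted p = 0.934), or 0.71 with a fixed total without hemoglobin, where the median of all genes was 0.51.

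**Figure D3:**
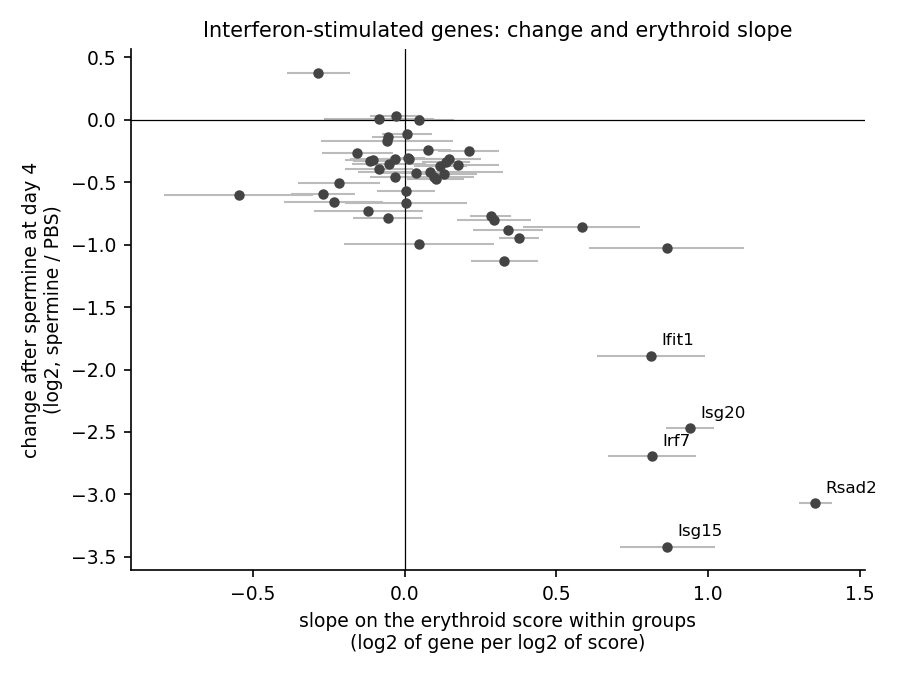
Log2 change after spermine on day 4 (6 spermine and 6 PBS mice, Ifnar1+/+) for each of the 48 interferon-stimulated genes (points) against the slope of the gene on the erythroid score within the 8 groups (bars, SE of the slope). Rsad2 has a slope of 1.35 and Isg15 a change of -3.42, and 45 of 48 changes lie below 0 in the main scaling, while the list median turns positive with a fixed total, which moves all genes alike, and stands at -0.36 relative to all genes without hemoglobin and -0.31 with it.

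Neutrophil genes were higher after spermine on day 4, such as Ly6g (1.40 ± 0.37), Csf3r, the receptor of the neutrophil growth factor (1.03 ± 0.18), and Cxcr2 (1.01 ± 0.17). Of 21 genes 15 rose and 6 were not called (18 rose adjusted over the list alone, median 0.99, camera adjusted p = 5.96e-16), list adjusted p = 0.0901 with an estimated correlation. In a test chosen after values were seen, adjusting for the erythroid score took the spermine difference of the neutrophil score from 0.86 ± 0.18 to 0.04 ± 0.22 (SE), with a slope of -0.35 ± 0.07 within groups. The erythroid scores of the spermine and PBS mice do not overlap (3.30 to 4.24 and 5.28 to 6.99). The adjustment thus extrapolates and cannot show that red-cell RNA accounts for the rise. In the list of neutrophil formation Ltf (-1.41 ± 0.28) and Camp (-1.26 ± 0.28), 2 of 6, fell (3 adjusted over the list alone, adjusted p = 0.055), and the median of -0.43 turned to 0.06 with a fixed total without hemoglobin (-0.44 relative to all genes). The inflammatory cytokine gene Il1b (1.10 ± 0.27) and Nlrp3 (0.84 ± 0.17), which governs its processing, rose, and the dismutase gene Sod2 (-0.93 ± 0.21) fell. In that NF-kB list 5 of 23 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.15, -0.01 without the 7 libraries of low mitochondrial share), list adjusted p = 0.318 with an estimated correlation. Of 16 cell cycle genes 8 fell (8 adjusted over the list alone), such as Ccna2 (-2.15 ± 0.33), list adjusted p = 0.0979 with an estimated correlation, and the median of -0.35 turned to 0.32 with a fixed total without hemoglobin (-0.19 relative to all genes). Among 24 components of JAK and STAT signalling 3 rose (3 adjusted over the list alone, median 0.10), such as the feedback inhibitor gene Socs3 (0.68 ± 0.18), list adjusted p = 0.376 with an estimated correlation. Il1b and Socs3 lost their calls without the 7 libraries of low mitochondrial share, and Ltf and Sod2 with a fixed total including hemoglobin.

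Polyamine genes had 1 up and 5 down of 18 after spermine on day 4 (1 and 5 adjusted over the list alone, adjusted p = 0.056). The spermine oxidase gene Smox (-2.20 ± 0.34), the antizyme genes Oaz1 (-2.08 ± 0.31) and Oaz2 (-1.05 ± 0.20) and the transporter gene Slc3a2 (-1.27 ± 0.21) fell, while Sat1 (0.45 ± 0.20, adjusted p = 0.193) and Odc1 (-0.28 ± 0.24, adjusted p = 0.619) were not called. The erythroid list fell in the same comparison (median -2.64). Smox was also lower on day 4 in mice labelled Ifnar1-/-, which had PBS and a lower erythroid list (-1.85). Whether the falls follow a lower share of red-cell RNA was not tested, so they cannot be read as a polyamine response to spermine. The list median of -0.06 turned to 0.54 with a fixed total without hemoglobin (0.03 relative to all genes). In all, 313 genes rose and 762 fell. With a fixed total without hemoglobin the split was 8015 and 486, and without the 7 libraries of low mitochondrial share 113 and 381. Without those libraries 6 neutrophil genes were up (median 0.46), 15 interferon-stimulated genes down (median -0.64) and 21 erythroid genes down (median -1.79).

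**Figure D4:**
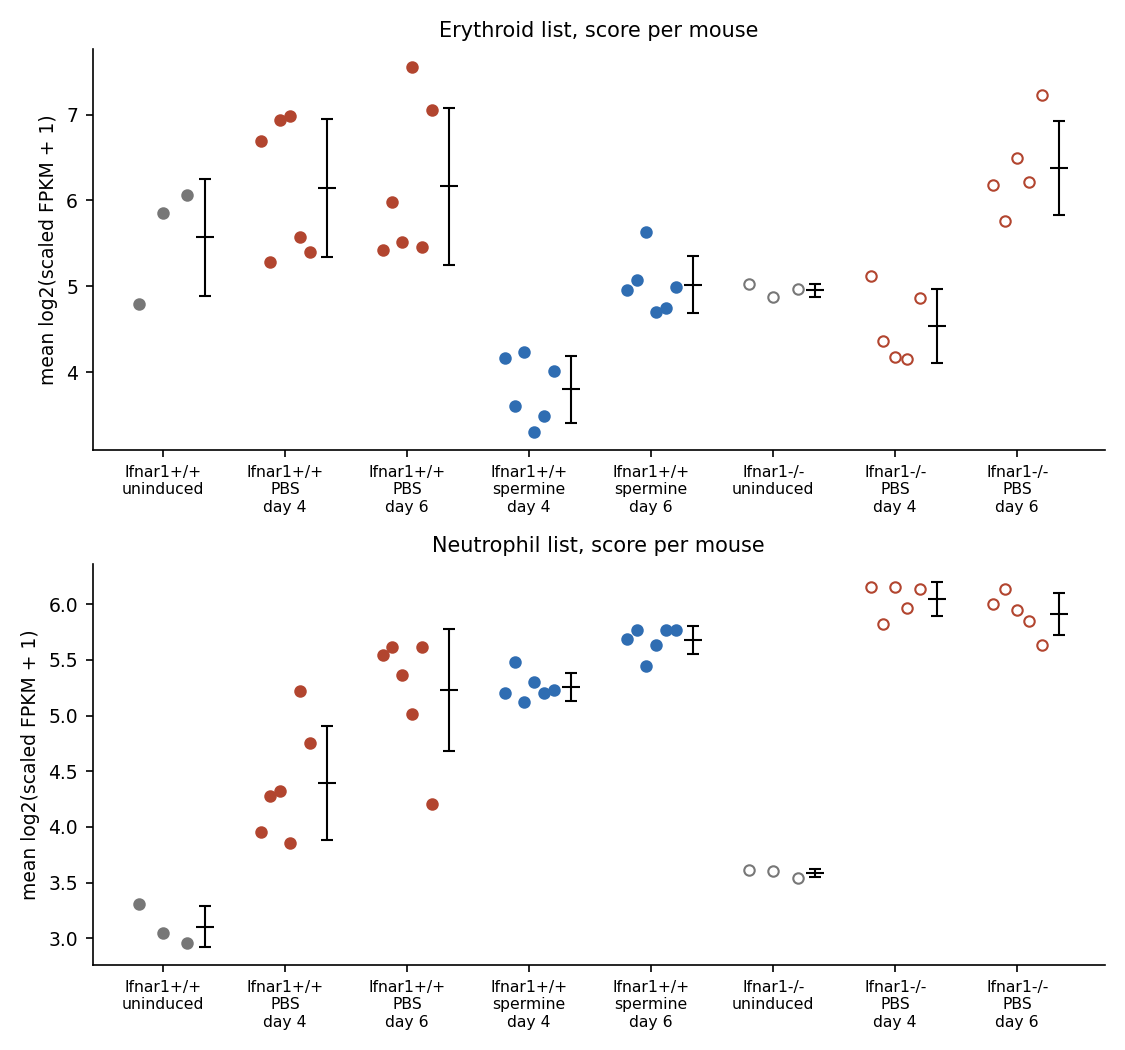
Mean log2(scaled FPKM + 1) of the erythroid list (25 genes, top) and the neutrophil list (21 genes, bottom) in each mouse (points: filled, Ifnar1+/+, open, labelled Ifnar1-/-, grey, uninduced, red, PBS, blue, spermine), with group mean and SD (bars). On day 4 the erythroid score averages 3.80 after spermine and 6.15 after PBS, and the neutrophil score 5.26 and 4.40.

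By day 6 few single genes differed between spermine and PBS, though red-cell genes were still lower as a group. Adjusted over the list alone 22 of 25 erythroid genes were lower (median -1.14, camera adjusted p = 6.74e-19), list adjusted p = 0.365 with an estimated correlation. The transferrin receptor gene Tfrc stood at -0.90 ± 0.21 (adjusted p = 0.051). Of 7 hemoglobin genes 5 were lower adjusted over the list alone (median -0.91), list adjusted p = 0.365 with an estimated correlation. Hemoglobin took 43.2 ± 6.17 percent of fragments against 51.3 ± 2.85 (exact permutation, two-sided, p = 0.0195, adjusted over 30 tests 0.0731). The interferon list had a median of 0.03 (adjusted p = 0.573, 5 lower adjusted over the list alone), with Isg15 at -1.40 ± 0.41 (adjusted p = 0.0807) and Irf7 at -1.25 ± 0.38 (adjusted p = 0.0886). Its score was 3.96 ± 0.18 against 4.06 ± 0.17 (exact permutation, two-sided, p = 0.336, adjusted 0.419). Limma called 5 genes (2 up, 3 down), and 1929 genes had an unadjusted p below 0.05. Miip (0.66 ± 0.13) and Tspan8 (-1.63 ± 0.32) met the naming rule, and Atic, Pde1b and Arl4a are named after their values were seen. Miip and Tspan8 lost their calls in a fit of only the groups compared and without the 7 libraries of low mitochondrial share. With a fixed total without hemoglobin the median of all genes was 0.28 and the split 211 and 128. The count of 5 was 288, 218 or 397 without PBS mouse 1, 3 or 5, 258 without spermine mouse 3, and 0 without PBS mouse 4 or 6 or spermine mouse 1, 4, 5 or 6 (limma, 1292 to 1906 genes at an unadjusted p below 0.05).

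The spermine effect was also compared between the days. Ucp2, a mitochondrial carrier gene, was less reduced on day 6 (2.04 ± 0.35, difference of log2 changes, adjusted p = 0.0061), at 101 ± 13.1 against 552 ± 109 scaled FPKM on day 4. The other of 2 genes called was 9530026F06Rik, named after its value was seen, and that count was 4 without PBS day 6 mouse 4. It was 12 with a fixed total without hemoglobin and 28 with hemoglobin included. With a fixed total without hemoglobin the median of all genes was -0.21, and relative to it the interferon list stood at 0.41. The interferon list differed by a median of 0.47 (camera, adjusted p = 2.77e-13), list adjusted p = 0.333 with an estimated correlation. Neutrophil, natural killer and mitochondrially encoded genes differed by medians of -0.43, -0.40 and -0.46. Their camera adjusted p values were 7.71e-07, 6.58e-08 and 2.6e-07, and none was called with an estimated correlation. Of 25 erythroid genes 16 were less reduced on day 6 adjusted over the list alone (median 1.45), list adjusted p = 0.333 with an estimated correlation.

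The spermine effect ran with the Ifnar1 genotype effect on day 4, where red-cell lists were lower and the neutrophil list higher in both. The covariance of the log2 changes over the 11772 genes was 0.183. Simulated unchanged groups that share 1 control group gave 0.0228 ± 0.0134 (SD), and the controls split 3 and 3 gave 0.156. The simulated mice were drawn from all 40 libraries, which did not keep the PBS libraries of low mitochondrial share together. The simulated values can therefore be too small for these controls. The correlation r was 0.81 (simulated 0.48, range -0.20 to 0.79 over 100 draws, split 0.64). Genes higher in both numbered 271 and lower in both 575, where independent lists would share 29.0 and 70.9, simulated unchanged groups gave 0 and 0, and split controls gave 120 and 230. On day 6 the covariance was 0.0354, against 0.0218 ± 0.011 simulated and 0.0104 with split controls. Against the pristane effect the day 4 covariance was -0.0534 (simulated -0.0251 ± 0.0201, split -0.0264) and that of day 6 -0.0274 (simulated -0.0212 ± 0.0136, split -0.0024).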

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

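The counts of other splits of the mice were planned, and the tests of explanations for the 3 patterns below were chosen after the patterns were seen. A mouse is listed here when its gap to the nearest other mouse, divided by the range of its group, passed the 95 percent critical value of Dixon's test. Among 198 such tests of 33 measures 19 passed, where 9.9 would by chance, about 1 in 20.

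The first pattern is the lower interferon-stimulated list after spermine on day 4. Low mitochondrial share in some PBS libraries is argued against, since the list median was -0.64 without the 7 libraries. The list score less the median of all genes in each mouse differed by -0.51 ± 0.19 (SE) with a fixed total including hemoglobin and by -0.55 ± 0.19 without it. This was chosen after the list median relative to all genes (-0.36) had been seen. Subtracting that median cancels the scaling of a library, apart from the 1 added before taking logs. The values thus show a list lower relative to other genes, but could not have pointed to the scaling and do not test it. For the sign of the list the scaling cannot be told apart from a fall, since the median of 0.15 with a fixed total without hemoglobin comes with 0.51 for all genes, and no value shows which total stayed constant. A lower share of red-cell RNA cannot be told apart from an effect on interferon signalling: adjusted for the erythroid score, the spermine difference of the list score went from -0.69 ± 0.19 to -0.36 ± 0.29 (SE). That difference and the slope within groups (0.14 ± 0.09) both lie within 2 SE of 0, which leaves this open, and the erythroid scores of the groups do not overlap (3.30 to 4.24 and 5.28 to 6.99). Rsad2 went from -3.07 to 0.10 ± 0.16 and Isg15 from -3.42 to -1.39 ± 0.48 in the same adjustment. Over the 48 members the median went from -0.45 to -0.27, 45 changes were below 0 before the adjustment and 40 after it, and 13 slopes were above and 4 below 0 by over 2 SE. After the adjustment 8 members lay below 0 by over 2 SE and none above.

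The second pattern is the lower erythroid list after spermine on day 4. The scaling is argued against, with a median of -1.70 at a fixed total of all fragments, and so are the PBS libraries of low mitochondrial share, with -1.79 without the 7 libraries. Fewer red cells of the same kind would lower erythroid and hemoglobin transcripts alike, but the erythroid score differed by -2.35 ± 0.35 and the mean log2 value of the 4 most abundant hemoglobin genes by -1.60 ± 0.31, a gap of -0.75 ± 0.26 (exact permutation, two-sided, p = 0.0325). Without the 7 libraries, 3 of them PBS mice on day 4, the gap was -0.30 ± 0.26 (exact permutation, two-sided, p = 0.369). Fewer red cells and a change in their kind thus cannot be told apart, since the gap rests on those 3 mice. Counts of red cells and reticulocytes would decide it.

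The third pattern is a high guanylate-binding protein list, of genes driven by interferon gamma, in 2 mice labelled Ifnar1-/-: day 4 mouse 1 (3.50) and day 6 mouse 3 (3.81), where the highest other mouse of that label was 2.61. A mislabelled genotype is argued against, since the lower of their Ifnar1 values was 15.9 FPKM and the highest Ifnar1+/+ mouse had 10.3. RNA from an Ifnar1+/+ mouse mixed in is argued against as the source of the Gbp2 values, at 115 and 104 scaled FPKM against 47.5 in the highest Ifnar1+/+ mouse. Mixed from that mouse, Gbp2 would need shares of 2.75 and 2.72, above 1. The 17 genes that separate the genotypes rose by a median of at most 0.0642 of what those shares would give. Since such shares cannot occur, that value adds nothing, and a smaller mix was not tested. No biological explanation was tested. In Ifnar1+/+ mice, day 4 PBS mouse 2 had 3.72.

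Other mice apart from their group are given as values only. In day 4 mouse 1 labelled Ifnar1-/- the interferon score was 3.11, the MHC class I score 5.50 and the cell cycle score 2.10. In day 6 mouse 3 labelled Ifnar1-/- the interferon score was 3.22, and in day 6 mouse 1 of that label the glycolysis score was 4.07. Day 4 mouse 4 labelled Ifnar1-/- had the Ifnar1 value of 23.9 FPKM. In day 4 PBS mouse 5 of Ifnar1+/+ the glycolysis score was 3.63. After spermine on day 4, mouse 6 had a neutrophil formation score of 1.96 and mouse 2 an oxidative phosphorylation score of 4.02 and a ribosomal protein score of 7.99. After spermine on day 6, mouse 1 had a Ly6C-high monocyte score of 3.57, and mouse 2 had MHC class I 5.75, unfolded protein response 3.74, oxidative phosphorylation 4.71, ribosomal proteins 8.59 and a mitochondrial share of 1.05 percent.

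Differences between groups in their response are listed as interactions. The genotypes differed in the pristane response at 30 genes on day 4 and 3 on day 6, with interferon list differences of -0.66 and -0.35, and the spermine effect differed between days at 2 genes with a list difference of 0.47. Other splits cannot decide on chance for these, since they exchanged pristane with uninduced mice, or spermine with PBS mice, within each genotype or day. A split that scrambles 1 side alone turns the effect of the other side into a difference. The highest other on day 4 kept all mice labelled Ifnar1-/- in their groups. As many genes came from 7 of 100 splits on day 4 (highest other 932), 5 of 100 on day 6 (558) and 5 of 100 for spermine by day (1022). For the list, 10 of 100 splits gave as large a difference on day 4 (highest other 1.02 against 0.66), 29 of 100 on day 6 (0.76 against 0.35) and 7 of 100 for spermine by day (0.62 against 0.47). The count of 30 on day 4 ranged from 1 to 128 with 1 mouse left out, with the mice named in the report.

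For the counts of genes, a share of splits under 0.05 with as many genes was set against chance. The shares are not adjusted over the contrasts. By this rule chance is taken as excluded for day 4 and day 6 of mice labelled Ifnar1-/- (1 of 56 splits each, 956 genes with highest other 317, and 1391 with 333). The same holds for genotype on day 4 (1 of 100, 2186, 1566) and day 6 (1 of 100, 377, 161), and for spermine on day 4 (1 of 100, 1075, 866). Pristane day 4 (2 of 84, 247, 1111) and day 6 (3 of 84, 966, 1161) have shares under 0.05 too. Chance is not taken as excluded for these 2, since other splits called more genes and a fixed total with hemoglobin left 16 and 57. By the same share spermine on day 6 would pass too (3 of 100, 5, 413), but chance is not taken as excluded there. Limma called 0 genes for it in a fit of only the groups compared (1406 at an unadjusted p below 0.05) and when any 1 of 6 of the 12 mice was left out (1292 to 1906). Chance is not excluded for day 6 against day 4 (6 of 100, 56, 1406). The uninduced genotypes have 10 splits, 1 as large (48, highest other 2), too few for a share under 0.05. The highest other split for pristane day 6 set the 3 mice of low mitochondrial share against the rest, and that for pristane day 4 set 3 of 4 such mice against the rest. Those for spermine on day 4 and for day 6 against day 4 put all such mice, 3 and 5, into 1 group beside 3 and 1 others. This points to a structure of the samples. Without the 7 libraries of low share the counts were 271, 682, 494 and 6. For the interactions other splits also called many times the real count. Those splits scramble the effects within a genotype or day, so their counts do not show a structure of the samples. Other splits called many times the real count for spermine on day 6 too, which points to some structure of the samples, and the cause was not tested. For spermine on day 6 the highest of them exchanged only PBS mouse 5 and spermine mouse 3, without which the count was 397 and 258.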

How the results depend on the processing

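The fixed total with hemoglobin, voom and the 7 libraries were chosen after results were seen, and the other settings were planned. The direction of the interferon list for pristane against uninduced mice and for genotype held under the scalings tried, but the number of genes called moved with most settings. The cause was not tested. FPKM as deposited moved no count. Among results of single genes, 26 lost their call with a fixed total without hemoglobin, 38 with hemoglobin included, 39 in a fit of only the groups compared, 23 without the 7 libraries, 11 with no filter, 8 with a pseudocount of 0.1, 8 with voom, 7 with the replicate block, 2 with arrayWeights and 1 with FPKM as deposited, each with its direction kept.

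A fixed total without hemoglobin gave 39 genes for pristane day 4, 158 for day 6, 2186 for day 6 in mice labelled Ifnar1-/-, 31 for the uninduced genotypes, 7050 and 152 for genotype on day 4 and day 6, 8501 and 339 for spermine on day 4 and day 6, and 12 for spermine by day. Limma then called 0 genes for day 6 against day 4 (970 at an unadjusted p below 0.05). The interferon list after spermine on day 4 turned to 0.15 (-0.36 relative to all genes), Jak1 to 0.71 and Odc1 to 0.47. With hemoglobin in the total the counts were 16, 57, 2362 (day 4 in mice labelled Ifnar1-/-), 323, 22, 9283, 84, 10016, 3738 and 28, with 574 for the genotype interaction on day 4, and 0 by limma for day 6 against day 4 (635 unadjusted). The list turned to 0.39 after spermine on day 4 and 0.033 in the genotype interaction on day 4. Jak1 turned to 0.99 and Odc1 to 0.75 after spermine on day 4, Odc1 to 0.040 for genotype on day 4, and Ifi209 to 0.12 for day 4 in mice labelled Ifnar1-/-.

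A pseudocount of 0.1 gave 15 genes for the genotype interaction on day 4 and 0 on day 6 (limma, 591 unadjusted). With no filter there were 139 for the uninduced genotypes and 10 for the genotype interaction on day 6. A fit of only the groups compared gave 17 and 441 for pristane day 4 and day 6, 1798 for day 4 in mice labelled Ifnar1-/-, 145 for genotype on day 6 and 14 for the interaction on day 4. That fit gave 0 by limma for the uninduced genotypes (1191 unadjusted), spermine day 6 (1406), day 6 against day 4 (1725) and the interaction on day 6 (558). With arrayWeights the counts were 379, 1607, 3105 and 3101 for pristane in the genotypes, 155 for the uninduced genotypes, 251 for spermine day 6, 148 for day 6 against day 4, 263 and 6 for the genotype interactions and 7 for spermine by day. Voom gave 114 for spermine day 6, 33 for day 6 against day 4, 0 and 1 for the genotype interactions (1027 unadjusted on day 4) and 6 for spermine by day.

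With the replicate number as a replicate block the count was 2 for spermine day 6 and 8 for the genotype interaction on day 4, and it changed no interferon list call and moved no other count by over 1.5 times. The labels do not say that the numbers pair the mice, and they were not treated as pairs. No contrast had every same-number pair above a correlation of 0.1, though 3 of 6 were for day 6 against day 4. This cannot exclude a pairing.

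With an estimated correlation the interferon list was not called at 0.72 (pristane day 4), 0.67 (day 6), 0.25 (day 6 labelled Ifnar1-/-), -0.77 (uninduced genotypes), -0.45 (spermine day 4), -0.66 and -0.35 (genotype interactions) and 0.47 (spermine by day). With the guanylate-binding protein list in its place the medians were 0.15 for pristane day 6, -0.047 for day 6 in mice labelled Ifnar1-/-, 0.28 for the uninduced genotypes, 0.14 for genotype on day 6, -0.23 for day 6 against day 4 and -0.32 for the genotype interaction on day 6.

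Without the 7 libraries of low mitochondrial share the list was 0.25 for day 6 in mice labelled Ifnar1-/- (adjusted p = 0.0875) and -0.19 for day 6 against day 4 (adjusted p = 0.00396). The counts were 2412 for day 6 in mice labelled Ifnar1-/-, 815 for genotype on day 4, 494 for spermine on day 4, 6 for day 6 against day 4, 9 and 5 for the genotype interactions and 1 for spermine by day, and 0 by limma for spermine day 6 (1037 unadjusted).

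Leaving out 1 mouse at a time, counts ranged from 113 to 288 for pristane day 4, 456 to 1092 for day 6, 701 to 938 and 722 to 1368 in mice labelled Ifnar1-/-, 27 to 54 for the uninduced genotypes, 1504 to 2572 and 231 to 379 for genotype on day 4 and day 6, 819 to 1277 and 0 to 397 for spermine, 24 to 339 for day 6 against day 4, 1 to 128 and 1 to 6 for the genotype interactions and 2 to 4 for spermine by day. The list ranged from 0.64 to 0.77 for pristane day 4, 0.56 to 0.77 for day 6, -0.12 to 0.13 and 0.10 to 0.32 in mice labelled Ifnar1-/-, -0.82 to -0.74 for the uninduced genotypes, -1.52 to -1.33 and -1.36 to -1.10 for genotype, -0.60 to -0.38 and 0.00 to 0.07 for spermine, -0.13 to 0.048 for day 6 against day 4, -0.97 to -0.60 and -0.57 to -0.29 for the genotype interactions and 0.42 to 0.65 for spermine by day. With the controls split 3 and 3, the covariances of the spermine effect were 0.156 and 0.0104 with the Ifnar1 genotype effect and -0.0264 and -0.0024 with pristane on day 4 and day 6.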

Other observations

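The gene lists here were planned and the reading of single genes was chosen after values were seen. Beyond the groups described, platelet genes were lower in mice labelled Ifnar1-/- than in Ifnar1+/+ mice on day 4, with 6 of 15 called (8 adjusted over the list alone), list adjusted p = 0.38 with an estimated correlation, and the median of -0.65 turned to 0.03 with a fixed total without hemoglobin (-0.42 relative to all genes). Wfdc17 (2.97 ± 0.42), Prok2 (2.71 ± 0.39) and Ifitm1 (2.70 ± 0.36) stood among the most raised genes. B cell genes had 8 of 17 lower (12 adjusted over the list alone), list adjusted p = 0.113 with an estimated correlation, and the median of -0.34 turned to 0.32 with a fixed total without hemoglobin (-0.13 relative to all genes).

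After spermine on day 4, the iron exporter gene Slc40a1 (1.09 ± 0.14) and the protease inhibitor gene Slpi (1.30 ± 0.29) rose, and Slpi lost its call without the 7 libraries of low mitochondrial share. Apol11b (-5.16 ± 0.58) and the blood group gene Kel (-3.25 ± 0.39) had among the lowest folds of the named genes. Apol11b varied widely among PBS mice, at 518 ± 608 scaled FPKM (mean ± SD, 6 mice), against 8.34 ± 3.27 after spermine.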
